A study of Pimephales promelas with 16 samples.

How the data were processed

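Total RNA of liver from male fathead minnows was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. Spot intensity was extracted by the authors with Feature Extraction version 10.7.3.1, per the file headers, which subtracts background, corrects spatial trends within the array and replaces very small values by a surrogate. The deposited intensity values are linear and not scaled between arrays. The deposited table of the whole series held the same intensity values: all 62372 features of each of the 16 arrays equalled the processed signal exactly, so its scale is linear, with no centring, and its column medians ran from 12.2 to 58.6. The quality metrics in the file headers were all in range for 15 arrays and out of range for 1, control replicate 1.

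Groups and replicate numbers were taken from the labels. The numbers differ between the groups and give no pairs. The design text calls the replicates biological, so each array was treated as 1 independent replicate; whether an array holds 1 fish or several is not given in the sources used here. Slide and position were read from the file names, and each of the 2 slides held 8 arrays of 1 group.

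Control spots and spots with an outlier flag were left out, saturation was checked, and the spots of 1 probe were averaged (41517 probes had 1 spot, 7973 had 2 and 359 had 10). Signals were taken as log2 of the processed signal minus the 75th percentile of the array. A probe was kept if at least 0.5 of its spots were well above background on at least 8 of the 16 arrays, whatever their group, which left 32580 probes. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. The number of arrays limits the precision. These choices, the gene lists and the alternatives were fixed before the data were examined, except where stated. Where a probe was not well above background on any array of a group, its fold was taken against a floor: the mean of the bright group was set against the mean, in the dim group, of the higher of the probe's own signal and the lowest signal well above background on the array. Such a fold depends on the treatment of background and is not a strict lower bound.

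Array measures were compared by exact two-sided permutation tests with scipy 1.17.1. The spike-in measure was the mean of 8 control probes with 35 spots each. Figures were drawn with matplotlib 3.10.9. On data simulated for the comparison of EE2 with control, with 32580 probes, the spread of the real probes and 200 probes changed, the fit found 16.2% of those changed by 1 log2 unit, 72.7% of those changed by 2 and 97.0% of those changed by 4, and 8 of its 131 calls were false (6.11%). The simulated noise was normal and drawn independently for each probe, whereas sets of real probes split the arrays alike. These rates may therefore not hold for the real data.

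The rule for naming was to describe genes of 39 fixed lists and the genes with the largest changes, and to report unnamed probes as a count with at most 2 that rose and 2 that fell. These are the probes with the largest fitted rise and fall, whether or not above background, among those with adjusted p under 0.05 and groups that do not overlap. None of the 49849 probe identifiers occurred in the reference table of 64593 genes or among the list members. The comparison by gene and the tests of the gene lists, fixed before, were therefore not run, and none of the 39 lists has a result. SINGLET_44980 was named outside the rule.

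The place of an array was computed for each array in the same way, leaving it out of both group means. For each choice of 2 control and 2 EE2 arrays, their mean difference was correlated across probes with that of the other 12 arrays. Alternatives were other scalings, normexp background correction with an offset of 50, other filters on dim probes, a variance trend with a robust prior, array weights, the row of the array on its slide as a covariate, and each array left out in turn. Leaving out 4 arrays, centring by GC content and using 1 probe per sequence were added after seeing the data. A fit with slide as a block was not possible, because each group lay on 1 slide.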

Results

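Liver RNA of male fathead minnows (Pimephales promelas, a small freshwater fish used in toxicity testing), was measured on Agilent 1-colour oligonucleotide arrays. The fish had been exposed to 17α-ethinylestradiol (EE2), the synthetic estrogen of contraceptive pills, at 25 ng/L for 96 h, or were controls. The labels gave 16 arrays, with 8 biological replicates labelled control and 8 labelled EE2. The series title places the arrays in a comparison between laboratories, of which 1 laboratory was analysed here. Each array held 61053 non-control spots of 49849 probes, and each probe was 60 bases long. The files name every probe only by a clone, contig or design identifier and describe it as unknown, so they do not pair probes with genes. No probe was assigned to a gene or to a place in the genome, and results are given by probe.

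The arrays differed widely in brightness within both groups. The 75th percentile of the processed signal ranged from 111 to 325 intensity units on the arrays labelled control and from 61.2 to 388 on those labelled EE2. On the log2 scale its mean was 7.48 ± 0.48 (SD, n = 8) for control and 6.97 ± 0.87 (SD, n = 8) for EE2, which did not differ by an exact two-sided permutation test (p = 0.169, adjusted p = 0.422 over 6 array measures). The share of probes well above background was 66.9% ± 4.7 (SD, n = 8) against 61.9% ± 9.5 (SD, n = 8), again without a difference by the exact permutation test (p = 0.211, adjusted p = 0.422). Local background was 19.3 ± 0.71 against 18.6 ± 1.85 intensity units (SD, n = 8 each, exact permutation p = 0.495, adjusted p = 0.585). Spike-in control probes, which measure RNA added before labelling, averaged 10.73 ± 0.63 against 10.06 ± 0.80 log2 units (SD, n = 8 each, exact permutation p = 0.0817, adjusted p = 0.422). After scaling, the spike-in difference, EE2 minus control, was −0.17 log2 units (exact permutation p = 0.585, adjusted p = 0.585). No spot was saturated on any array. All 8 arrays labelled control lay on 1 slide and all 8 labelled EE2 on another, so slide and treatment cannot be told apart in any comparison of the groups.

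**Figure D1:**
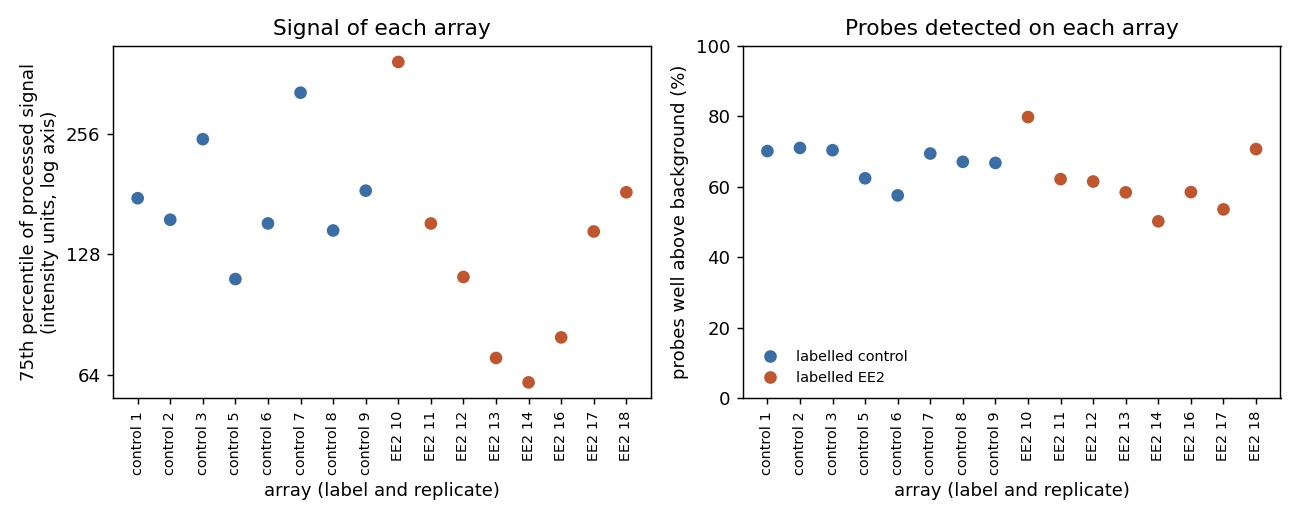
Left, the 75th percentile of the processed signal of each array (intensity units, log axis); right, the percentage of probes well above background; each point is 1 array, coloured by its label. The signal runs from 61.2 to 388 and the share of probes detected from 50.2% to 79.8%, both extremes being arrays labelled EE2.

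The comparison of the groups asked which liver transcripts changed after exposure to EE2. Of 32580 probes tested, 455 (1.40%) differed significantly between the arrays labelled EE2 and control, with 150 higher and 305 lower in those labelled EE2 (limma, adjusted p under 0.05). The excess of falls depended on the filter on dim probes, as 273 were higher and 252 lower without it, and 198 higher and 218 lower among probes well above background on all 16 arrays. The absolute log2 change of these probes had a median of 1.54 and ranged from 0.77 to 4.70. A change of at least 2-fold was met by 429 of them, 134 higher and 295 lower. The 455 probes held 424 distinct sequences. Probes that fell were dim, with a median signal of −2.16 log2 units relative to the 75th percentile of the array, against −0.62 for those that rose and −1.11 for all tested probes. The groups did not overlap for 91 of the 455 probes and for 120 of all tested (0.368%, where chance gives 0.0155% for 8 against 8).

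The probe UF_Ppr_AF_118664 (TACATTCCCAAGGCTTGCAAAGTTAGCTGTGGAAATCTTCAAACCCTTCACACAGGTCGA) rose most among the probes whose groups did not overlap. Its signal was 2.05 ± 1.73 on the arrays labelled EE2 and −2.06 ± 1.16 on those labelled control (log2 relative to the 75th percentile, SD, n = 8 each). The groups lay only narrowly apart, with EE2 replicate 18 at −0.27 and control replicate 5 at −0.33. The difference of the means was 4.11 ± 0.67 (SE) on the log2 scale, or 17.3-fold (limma adjusted p = 0.0212, higher in 8 of 8 arrays). With a model-based background correction (normexp) it was smaller, at 2.94 after 75th percentile scaling and 2.78 after quantile normalization, and it was 4.99 without the 4 arrays described further on. SINGLET_33342 (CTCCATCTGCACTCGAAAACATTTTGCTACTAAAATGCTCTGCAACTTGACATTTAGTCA) rose by 2.70 ± 0.50 (SE, adjusted p = 0.0272), from −5.17 ± 1.04 to −2.47 ± 1.12 (SD, n = 8 each). It was well above background on only 3 arrays labelled control and 5 labelled EE2. EE2 replicates 13, 14 and 16, at −3.78, −3.69 and −3.18, were not, and the nearest array labelled control read −3.87. These EE2 arrays had low 75th percentiles (70.4, 61.2 and 79.3 intensity units), and subtracting a low percentile raises values near background. The separation of the groups may therefore rest on the scaling. The call of SINGLET_33342 was lost without control replicate 2 or 9 or EE2 replicate 11 or 12 (adjusted p from 0.053 to 0.0602). The size of its rise depended on the treatment of background: with normexp it was 0.84 after 75th percentile scaling (adjusted p = 0.0389) and 0.55 after quantile normalization, where it did not pass (adjusted p = 0.0823).

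SINGLET_32203 (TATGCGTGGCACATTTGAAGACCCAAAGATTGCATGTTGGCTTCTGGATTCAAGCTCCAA) fell with the smallest adjusted p of all tested probes, from −2.23 ± 0.46 on the arrays labelled control to −5.22 ± 0.73 on those labelled EE2 (SD, n = 8 each, adjusted p = 0.000583). It was well above background on all 8 arrays labelled control and not well above background on any labelled EE2. Its fold was therefore taken against the floor, which gave a 4.47-fold higher signal in control. This is not a lower bound, because with normexp the log2 difference was far smaller. It was −0.33 after 75th percentile scaling, where the call was lost (adjusted p = 0.425), and −0.56 after quantile normalization, where it held (adjusted p = 0.0105). SINGLET_47723 (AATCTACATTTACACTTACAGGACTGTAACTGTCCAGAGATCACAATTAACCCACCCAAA) fell by 2.98 ± 0.51 (SE) on the log2 scale, or 7.90-fold, from 1.88 ± 0.81 to −1.10 ± 1.31 (SD, n = 8 each, adjusted p = 0.0221, lower in 8 of 8 arrays). With normexp the log2 difference was −2.07 after 75th percentile scaling and −2.17 after quantile normalization. It was measured well above background on 8 arrays labelled control and 7 labelled EE2.

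**Figure D2:**
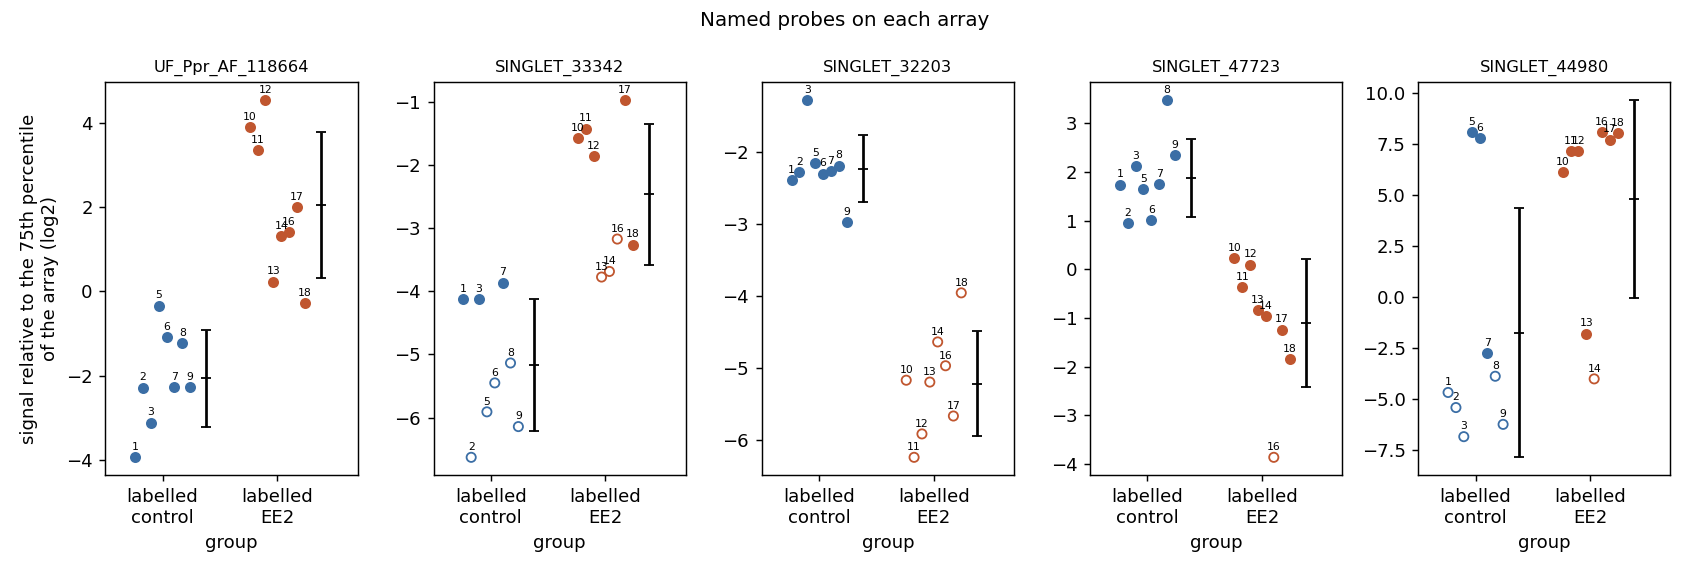
Signal of 5 probes on each array, as log2 relative to the 75th percentile of the array, by label; numbers are replicates, filled points are well above background, open points are not, and bars give the mean ± SD of 8 arrays. The groups do not overlap for the first 4 probes, though only narrowly for UF_Ppr_AF_118664 (EE2 replicate 18 at −0.27, control replicate 5 at −0.33). For SINGLET_33342 the separation is also narrow, with values near background. For SINGLET_44980, control replicates 5 and 6 sit at 8.11 and 7.82, among 6 of the EE2 arrays. EE2 replicates 13 and 14 sit at −1.78 and −4.0, against −6.84 to −2.74 for the other 6 control arrays.

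The largest differences were not among the probes that passed the test. An absolute log2 difference of at least 3 was estimated for 117 probes, of which 16 passed. SINGLET_44980 (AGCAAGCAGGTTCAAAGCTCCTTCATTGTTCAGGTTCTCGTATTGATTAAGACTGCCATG), chosen after its values were seen, had the largest estimate of all tested probes, 6.55 ± 2.48 (SE) on the log2 scale, and did not pass (adjusted p = 0.143). Its spread within the groups was large, at −1.73 ± 6.12 for control and 4.83 ± 4.84 for EE2 (SD, n = 8 each). It was well above background on only 3 arrays labelled control and 7 labelled EE2, so the size of the estimate and its rank rest partly on values near background. A gap of at least 4 log2 units, with at least 3 arrays on each side, separated the arrays for 97 of 32488 probes with values on all 16 arrays. In 36 of these 97 probes, with 34 distinct sequences, the same 8 arrays were high: EE2 replicates 10, 11, 12, 16, 17 and 18 and control replicates 5 and 6. The median signal of the 36 probes was 7.35 on control replicate 5 and 6.63 on control replicate 6, and it lay between 5.83 and 6.63 on the 6 high EE2 arrays. It was −2.37 on EE2 replicate 13 and −3.94 on EE2 replicate 14, against −4.46 to −2.40 on the other 6 control arrays. None of the 36 probes passed the limma test between the groups (32 had an unadjusted p under 0.05), with estimates from 2.77 to 6.55 and adjusted p from 0.102 to 0.262. The gap lay between the labelled groups in 0 of the 97 probes.

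**Figure D3:**
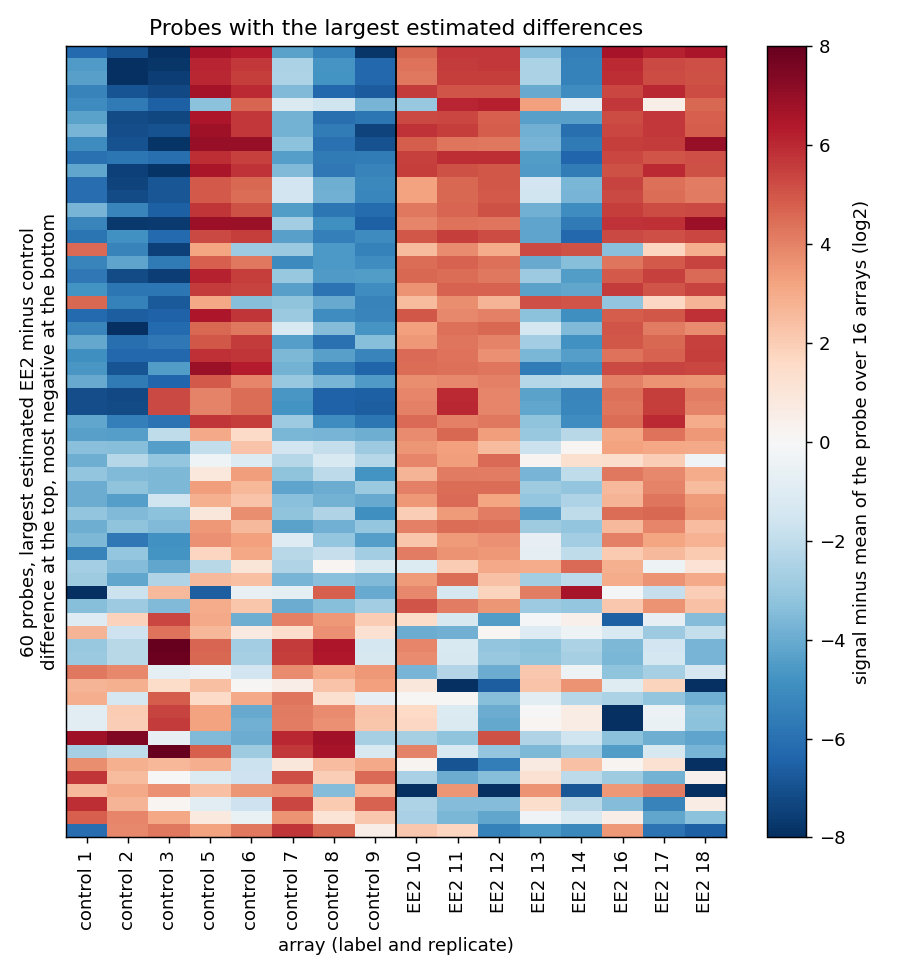
The 60 probes with the largest estimated differences between labels (rows) on the 16 arrays (columns); colour is the log2 signal minus the mean of the probe over all arrays, with the scale ending at −8 and 8. Of the 60 probes, 43 have an estimate above 0 and 17 below 0, and 6 passed the test; in most of the upper rows control replicates 5 and 6 are red like 6 of the EE2 arrays, and EE2 replicates 13 and 14 are blue like the other control arrays.

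Each array was also placed between the mean of the other control arrays (0) and that of the other EE2 arrays (1), over the probes for which those means differed by at least 3 log2 units. The median place was −0.44 to 0.01 for control replicates 1, 2, 3, 7, 8 and 9. It was 0.91 for control replicate 5 (quartiles 0.09 and 1.42, 149 probes) and 1.16 for control replicate 6 (quartiles 0.82 and 1.42, 172 probes). It was 1.01 to 1.43 for EE2 replicates 10, 11, 12, 16, 17 and 18, but −0.03 for EE2 replicate 13 (quartiles −0.24 and 0.50, 153 probes) and −0.07 for EE2 replicate 14 (quartiles −0.36 and 0.54, 162 probes). The labels of these 4 arrays are therefore in doubt, that of control replicate 5 least clearly, and every direction given here is between the arrays as labelled. The lowest 75th percentile of each label was among them, at 111 intensity units on control replicate 5 and 61.2 on EE2 replicate 14. So was the lowest share of probes well above background of each label, 57.6% on control replicate 6 and 50.2% on EE2 replicate 14. Whether this bears on their places was not tested. Without the 4 arrays, an alternative chosen after seeing the data, 6302 probes passed, 2741 higher and 3561 lower, and 443 of the 455 were among them. The 4 arrays were picked for levels against their label, so a higher count without them was favoured by the choice and does not test the labels. The count otherwise depended on single arrays. It was 31, 33, 66, 192, 1289, 156 and 68 without control replicates 1, 2, 3, 5, 6, 7 and 9, and 113, 41, 41, 1038, 1961, 229 and 761 without EE2 replicates 10, 11, 12, 13, 14, 16 and 18.

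**Figure D4:**
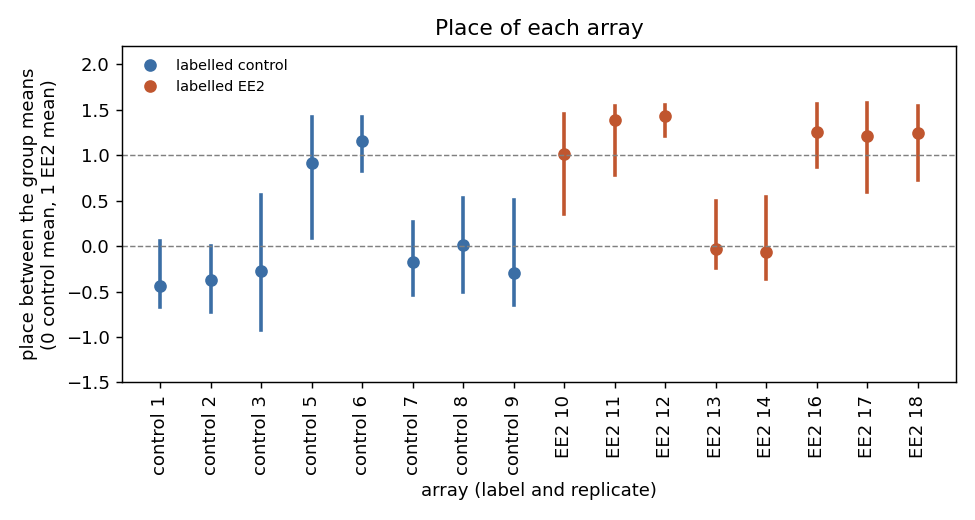
Median place of each array (point) with quartiles over probes (line), where 0 is the mean of the other control arrays and 1 that of the other EE2 arrays; colours give the label. Control replicates 5 and 6 are at 0.91 and 1.16, near the EE2 mean, and EE2 replicates 13 and 14 at −0.03 and −0.07, near the control mean.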

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

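All tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the arrays, whose rule was set earlier and whose prediction was written after a first draw.

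3 of 22 groups of array values held an array far from the other 7 of its label, where chance gives about 1 in 20. The mean of the spike-in probes was 11.86 log2 units on EE2 replicate 10, with the nearest array labelled EE2 at 10.29. The spike-in mean relative to the 75th percentile was 1.96 on EE2 replicate 18, with the nearest at 3.0. Control replicate 6 had 319 outlier spots, with the nearest array labelled control at 216.

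Control probes taken to detect no fish RNA lay outside the comparisons, and some read above every array labelled control on arrays labelled EE2. Whether any of them binds fish RNA was not tested, and ERCC-00062_278 read 4.71 to 6.91 log2 units before scaling on the arrays labelled control. The probe ERCC-00043_129 read −2.01 on EE2 replicate 16 and −3.41 on replicate 18, against −6.65 to −5.17 on the arrays labelled control (log2 relative to the 75th percentile). ETG10_234183 read −2.29 and −3.10 on the same 2 arrays, against −6.80 to −5.04. Both probes were above the control arrays before scaling too, at 4.30 and 4.10 against at most 2.09, and at 4.02 and 4.42 against at most 3.16 (log2 signal). On replicate 16, ETG05_36762 read −4.24, ETG07_105829 −4.26 and ETG10_195139 −4.52, with highest control values of −5.52, −5.59 and −5.49, but before scaling none of these 3 exceeded the control arrays except ETG07_105829 (2.05 against 2.03). After scaling, 1, 0, 1, 15, 20, 20, 1 and 5 of 25 such probes lay above all control arrays on EE2 replicates 10, 11, 12, 13, 14, 16, 17 and 18. Before scaling, 4 did on each of EE2 replicates 10, 16 and 18 and 0 on the other 5 arrays labelled EE2. The 75th percentiles of replicates 13, 14 and 16 were low, at 70.4, 61.2 and 79.3 intensity units, and subtracting a low percentile raises values near background. None of 33 control probes passed the limma test between the groups (3 had an unadjusted p under 0.05).

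Control replicates 5 and 6 carried the levels of most EE2 arrays in the most divergent probes, and EE2 replicates 13 and 14 those of most control arrays. The case was weakest for control replicate 5, whose places had quartiles of 0.09 and 1.42. The count of 455 changed probes fell to 192 without control replicate 5. It rose to 1289, 1038 and 1961 without control replicate 6, EE2 replicate 13 and EE2 replicate 14. A difference between the slides as the whole cause is argued against, because the places of the arrays on the control slide alone spanned 1.60 between the group means. A candidate explanation is an exchange of samples or labels between the groups. The 462 probes that had a gap of at least 2 log2 units between arrays or entered the places were set aside. Over the other 32026 probes, the difference between labels in these 4 arrays still ran against that in the other 12. Pearson r was −0.236, against −0.303 with all probes, which are not independent replicates. The r of −0.236 was the lowest of all 784 choices of 2 control and 2 EE2 arrays (median 0.428, highest 0.629). However, the 4 arrays were picked on the same data, and the probes left are not independent of those set aside. This rank is therefore no independent test of an exchange. A differing response to EE2 could not by itself raise control replicates 5 and 6, because control fish were not given EE2. Fish whose levels differed within both groups for any reason cannot be told apart from an exchange, since both give levels of the other label in both groups. The lowest EE2 array in the 36 probes of the shared split, at −3.94, lay within the control arrays. These probes were picked by that split, so the value cannot decide between the 2, and the biological explanation stays untested. That the 4 arrays hold the same 2 positions on both slides, 1 of 28 possible pairs of positions, was noticed after they were picked and does not exclude it.

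Of the 455 probes that passed the test, 91 kept all 8 arrays of each label apart, the 4 arrays in doubt included. Chance as the cause is argued against only weakly and is not excluded. Of 100 splits of the 16 arrays, the real one included, 3 gave at least 455 probes, and 3 gave at least the 429 changed at least 2-fold. The prediction was written after a first draw. The count of 455 fell to 31, the lowest with 1 array left out, without control replicate 1, the only array with quality metrics out of range. It fell to 33 without control replicate 2, whose metrics were in range. The highest other splits gave 4704 and 3350, several times the real counts, in a split that exchanged control replicates 6 and 7 with EE2 replicates 13 and 14, which points to a structure of the samples that the labels do not follow. GC content as the whole cause is argued against, because 390 of the 455 remained once each array was centred by GC class. A part is not excluded, since before centring the log2 change fell with GC content across tested probes (Spearman rho −0.186). With centring 578 probes passed, 39.8% of them higher, against 33.0% without. A difference between the slides cannot be told apart from EE2, because each slide held 1 group. The smallest adjusted p among the control probes was 0.0622 (limma). If samples were exchanged before labelling, these 91 probes may follow the slide and not the treatment, which stays open.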

How the results depend on the processing

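The settings without 4 arrays, with centring by GC class and with 1 probe per sequence, and all settings for the split of the arrays, were chosen after seeing the data. The count of 455 changed probes (429 at least 2-fold) moved by over 1.5 times in the settings that follow, except where stated, and where no reason is given the cause was not tested. With normexp and 75th percentile scaling it was 203 (146 at least 2-fold), and with normexp and quantile normalization the 2-fold count was 120. With array weights it was 3605 (2787). At adjusted p under 0.01, a stricter threshold, it was 4. Leaving out 1 array at a time gave 31 to 1961 (31 to 1666). Without control replicate 8 or EE2 replicate 17 it stayed within 1.5 times, at 344 and 345. The other counts by array were 31, 33, 66, 192, 1289, 156 and 68 without control replicates 1, 2, 3, 5, 6, 7 and 9, and 113, 41, 41, 1038, 1961, 229 and 761 without EE2 replicates 10, 11, 12, 13, 14, 16 and 18. Without the 4 arrays in doubt it was 6302 (4893). Leaving out 99 other drawn choices of 2 control and 2 EE2 arrays gave 0 to 4509, the highest with 3 of the 4. The 4 arrays were picked on these data for levels against their label, so a higher count without them was favoured by the choice. The contrast is no test of the labels. The other settings gave 392 to 663. The series table gave 455, its values being identical. Without the dim filter 273 probes were higher and 252 lower, and among probes above background on all 16 arrays 198 were higher and 218 lower, so the excess of falls depends on the filter. Normexp with 75th percentile scaling shifted the median log2 change of all probes to 0.12. The fall of SINGLET_47723 and the rise of UF_Ppr_AF_118664 passed at adjusted p under 0.05 in all settings that tested them, but neither passed the stricter threshold of 0.01 in the main fit. The difference of SINGLET_44980 passed in 2 of 28 settings, with array weights and without the 4 arrays, where the choice of arrays fixed the outcome. The 36 probes of the shared split were 25 with normexp, 11 among probes above background on all 16 arrays and 36 to 38 otherwise. The 4 arrays kept a negative correlation with the other 12 under all 5 settings tried (−0.428 to −0.165). Signal over background limits the dim probes, and 3 that fell were not well above background on any array labelled EE2. No paired analysis was possible because the groups share no replicate numbers. Slide as a block, and the alternatives for genes and gene lists, were not run.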

Other observations

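The test of position in this part was chosen after the result was seen. A second set of 8 probes, with 6 distinct sequences that form 3 groups sharing runs of at least 25 bases, was on or off on single arrays without regard to the label. Its median signal was between 7.95 and 10.11 on control replicates 1, 3, 5 and 6, and between 8.44 and 11.54 on EE2 replicates 10, 12, 14 and 18. On the other arrays it lay between −5.30 and −0.81. A local fault on the arrays is argued against, because the probes were spread out: 85.5% of 10000 random sets of 8 probes lay closer together. No biological explanation was tested, since the design gives no group that follows this split. The remaining 53 of the 97 probes with a gap of at least 4 log2 units fell into 33 other splits.

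The array prints 5131 sequences under more than 1 probe name, which gives a measure of technical error within arrays, but not of error between arrays or slides. Over 3399 such pairs among the tested probes, the log2 changes correlated with r = 0.959 across pairs, which are not independent replicates, and their difference had an SD of 0.203. Both members passed in 31 pairs and 1 member alone in 36.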
